A study of Mus musculus with 10 samples.

How the data were processed

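RNA was profiled from 10 libraries of fluorescence-sorted mouse brain cells. Per the labels, each library came from GFP-positive cells pooled from 3 to 4 animals, collected 1 month after an adeno-associated virus (AAV) had been placed in the dentate gyrus of the hippocampus. The viruses carried a Cre-dependent (FLEX) cassette of GFP alone or of GFP with a TDP-43 form named mNLS. The recipients carried the neuronal driver CamKII-Cre, alone (control) or with both copies of the TDP-43 gene flanked by loxP sites (TDP-43cKO). RNA was extracted with a micro column kit, and 1 ng of it entered a stranded SMART-Seq library, per the labels' protocols. Because libraries are pools, the p-values measure the spread between pools and not between single animals.

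The deposited table listed 55487 genes with an estimated count and a TPM value for each library, per the file headers. The estimated counts of the authors were not normalized, and 5.84% of the values were not whole numbers. The TPM values were scaled by the authors for transcript length and library total and were not used for any test here. DRAGEN and the genome build GRCm38/mm10 are named per the submitters' processing notes. The version, the annotation release, the counting settings and the use of strand are not given in the sources used here. Gene identifiers, symbols and coordinates were taken from the deposited table. The table used 114 symbols for more than 1 gene, and tests were therefore run by gene identifier. Each column was assigned to its library by its name, and group membership came from the labels.

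Estimated counts were rounded to whole numbers. Library totals lay between 17164162 and 29204279 counts. Low-count genes were removed with the group-wise filter of edgeR, which left 20379 genes holding at least 99.83% of the counts in each library. The primary test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM scaling and robust estimation, in 1 model of the 3 groups with 7 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.406. CPM values used the TMM-scaled totals, and log2 fold changes are given with their standard errors (SE). Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts over the group, which covers counting error only.

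The 30 gene lists covered TDP-43 and other RNA-binding proteins, genes reported with TDP-43 cryptic exons in mouse, neuronal functions, markers of glial, vascular, blood and inhibitory cells, cell states and RNA quality. They were drawn from memory. Of the 38 long-intron genes 14 are in another list, as are 7 of 36 synaptic adhesion genes, 11 of 37 axon-glia genes and 2 of 32 presynaptic genes, while the 16 astrocyte markers are in no other list. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 30 lists. The camera test with an estimated correlation and the rotation test fry were alternatives. Long genes were the 10% of tested genes with the longest genomic span. The groups, tests, gene lists, the rule for named genes and most other settings were fixed before the data were examined.

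The rule for named genes took Tardbp in each comparison. Some genes that the rule names are not reported here. It added the 8 rising and the 8 falling genes of smallest p with an absolute log2 fold change of at least 1 and no overlap of the groups in CPM, leaving out predicted and pseudogene symbols. It also took up to 3 members of smallest p from each list that passed its test and from each list about TDP-43 or about other cell types. For the genes that moved back it took the 8 of smallest p. Genes outside this rule are said to have been chosen after their values were seen.

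Other settings chosen beforehand were the size factors of DESeq2 within edgeR, the DESeq2 Wald test (version 1.42.0), limma voom with sample quality weights, no low-count filter, a stricter filter (CPM of at least 1 in at least 6 libraries), a fit of only the compared groups, a fit with the replicate number as a block, and each library left out in turn. Covariates for the astrocyte and the presynaptic list level, and leaving out mitochondrial genes, were added after seeing the data.

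The steps were tested on simulated counts drawn from the means and sizes of the real libraries, with 100 genes changed at each size. For cKO-GFP against NC-GFP (19739 genes), edgeR recovered 10% of genes changed by a log2 fold change of 1 and 64% of those changed by 2, and 5.1% of its calls were unchanged genes. For cKO-mNLS against cKO-GFP (19746 genes) the shares were 17%, 70% and 3.3%, and for cKO-mNLS against NC-GFP they were 26%, 69% and 8.7%. DESeq2 called more unchanged genes, 35.5%, 26.9% and 23.8% of its calls in the same order, and voom with quality weights 4.1%, 1.2% and 7.7%. Replicates of a group were compared for duplicated libraries. The chi-square statistic per degree of freedom was 24.8 or more for every pair within a group, so no pair was alike within sampling noise and all 10 libraries were counted. Sequences of mt-Nd3 and its nuclear copy were aligned with Biostrings 2.70.1, using GENCODE transcripts of the mouse.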

Results

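The data were gene counts from GFP-positive cells sorted from mouse brain. TDP-43, encoded by Tardbp, is an RNA-binding protein that acts in splicing and RNA stability. The study asked how neuronal TDP-43 bears on myelin. There were 3 groups: control mice given the GFP vector (NC-GFP, n = 3), TDP-43cKO mice given the GFP vector (cKO-GFP, n = 3) and TDP-43cKO mice given the TDP-43mNLS vector (cKO-mNLS, n = 4). Totals were 24059526, 26310751 and 17164162 counts in the NC-GFP libraries, 29204279, 25404097 and 27808757 in cKO-GFP, and 28187096, 19826477, 24552849 and 28065422 in cKO-mNLS. Mitochondrial genes held 10.9% to 16.5% of the counts. Within groups, log2 CPM correlated across genes at 0.949 to 0.952 in NC-GFP, 0.948 to 0.96 in cKO-GFP and 0.912 to 0.941 in cKO-mNLS, where genes are not independent replicates. The first principal component held 40% of the variance, and it placed the 4 cKO-mNLS libraries at 56.5 to 116.1 and the other 6 at -82.1 to -27.1.

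Tardbp (ENSMUSG00000041459.15; GRCm38/mm10 chromosome 4, 148612382 to 148627019, minus strand), the targeted gene, stood at 143, 128 and 121 CPM in the libraries labelled NC-GFP. It stood at 120, 122 and 108 CPM in those labelled cKO-GFP and at 206, 218, 337 and 185 CPM in those labelled cKO-mNLS. The group means were 131 ± 11.3 (SD, n = 3), 117 ± 7.75 (SD, n = 3) and 237 ± 68.5 (SD, n = 4) CPM. The cKO-GFP value did not differ from NC-GFP (log2 fold change -0.16, SE 0.205, adjusted p = 0.745). The gene was higher in cKO-mNLS than in cKO-GFP (log2 fold change 1.02, SE 0.196, adjusted p = 0.00642) and than in NC-GFP (0.86, SE 0.195, adjusted p = 0.0149). The call against NC-GFP was lost without NC-GFP replicate 2 (0.86, adjusted p = 0.0625) and without NC-GFP replicate 3 (0.80, adjusted p = 0.0809). Which part of Tardbp is deleted, and whether reads of the viral construct count toward it, are not given in the sources used here, so these counts do not check the genotype labels.

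Markers of glia were abundant in the sorted cells of all groups, and markers of neurons were low in the groups given GFP alone. This is not what a neuronal driver with a Cre-dependent vector would give in pure sorted cells, and the sort gates are not given in the sources used here, so which cells carried the deletion is not known. The neuronal and glial genes in this paragraph other than P2ry12 were chosen after their values were seen. Mbp, the myelin basic protein gene of oligodendrocytes, stood at 1701 ± 200.2 (SD, n = 3) CPM in NC-GFP, 1508 ± 401 (SD, n = 3) in cKO-GFP and 1310 ± 413 (SD, n = 4) in cKO-mNLS. The microglial receptor gene P2ry12 stood at 343 ± 34.7, 211 ± 78.3 and 113 ± 48.8 CPM in the same order. Snap25, a neuronal gene of synaptic vesicle fusion, stood at 6.35 ± 1.79, 13.2 ± 6.57 and 156 ± 91.5 CPM. The excitatory vesicular glutamate transporter gene Slc17a7 stood at 0.403 ± 0.527, 4.33 ± 2.95 and 85.0 ± 51.2 CPM. Prox1, which marks dentate granule neurons and is also expressed by oligodendrocyte lineage cells, stood at 198 ± 21.3, 159 ± 47.2 and 214 ± 71.9 CPM.

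**Figure D1:**
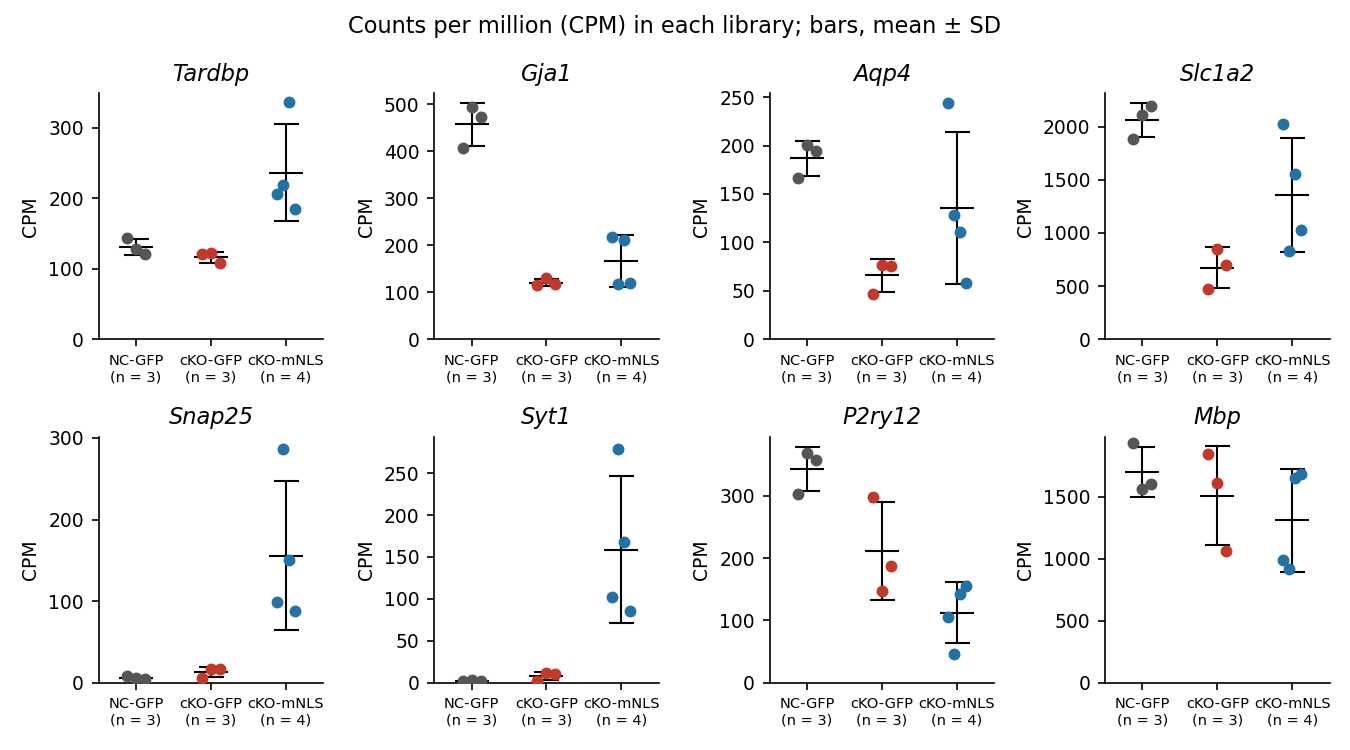
CPM of 8 genes in each library of NC-GFP (n = 3), cKO-GFP (n = 3) and cKO-mNLS (n = 4), with linear axes from 0; points are libraries, bars the mean ± SD. Gja1 and Aqp4 are lower in all 3 cKO-GFP libraries than in all 3 NC-GFP libraries, and Snap25 and Syt1 are above 85 CPM only in cKO-mNLS.

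The TDP-43cKO label was compared with the control label among mice given GFP alone, in cKO-GFP against NC-GFP, where Tardbp itself did not differ. Most markers of astrocytes were lower in cKO-GFP. Of 16 measured, 6 fell and 0 rose (14 fell adjusted over the list alone), with a median log2 fold change of -1.30. The gap junction genes Gja1 (457 ± 45.8 to 121 ± 8.09 CPM, n = 3 each; -1.92, SE 0.25, adjusted p = 0.00623) and Gjb6 (-1.96, SE 0.281, adjusted p = 0.00763) were among them. The list passed camera (adjusted p = 1.19e-18; adjusted p = 0.708 with an estimated correlation).

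Some genes of cell contact and of GABA receptors fell in 4 further lists, most of whose members were not called. Of 38 long-intron neuronal genes, 4 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.57, camera adjusted p = 1.07e-07). The cell adhesion gene Lsamp fell by 1.51 on the log2 scale (SE 0.204, adjusted p = 0.00722) from 126 ± 11.4 to 44.3 ± 2.54 CPM (n = 3 each). Synaptic adhesion genes gave 4 falls and 1 rise among 35 (6 and 1 adjusted over the list alone; median -0.26, camera adjusted p = 0.00148), led by Slitrk2 (-2.12, SE 0.249, adjusted p = 0.00442). Genes of axon-glia contact and myelin signals gave 4 falls and 1 rise among 37 (5 and 1 adjusted over the list alone). Their median was -0.05, their mean 0.06 and their test negative (camera adjusted p = 0.0278). Lgi1, which encodes a secreted synaptic protein, fell in this list (-1.94, SE 0.241, adjusted p = 0.00563). Receptors for the inhibitory transmitter GABA gave 3 falls among 15 (5 falls and 2 rises adjusted over the list alone), with a median of -0.34, a mean of 0.21 and a negative test (camera adjusted p = 0.0278). With an estimated correlation, the adjusted p was 0.708 for each of these 4 lists. The mean level of the long-intron list differed by -0.46 and by -0.28 without cKO-GFP replicate 1. That of the synaptic adhesion list differed by -0.17, and by -0.10, -0.30 and -0.10 without cKO-GFP replicates 1, 2 and 3. The axon-glia list was not called without NC-GFP replicate 1 (adjusted p = 0.111) or without cKO-GFP replicate 1 or 3 (0.181 and 0.180), nor the GABA list without NC-GFP replicate 2 (0.109) or cKO-GFP replicate 1 (0.50). The astrocyte list moved the same way in the same libraries, with a median of -1.30, while presynaptic release genes had a median of 0.36 (camera adjusted p = 0.266).

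Among other genes that fell were Fut9, which encodes a fucosyltransferase (66.9 ± 2.39 to 14.1 ± 0.527 CPM, n = 3 each; -2.25, SE 0.168, adjusted p = 3.74e-04), the proteoglycan gene Cspg5 (-1.75, SE 0.174, adjusted p = 0.00171), Mfge8 (-1.70, SE 0.176, adjusted p = 0.0022), the cystine transporter gene Slc7a11 (-1.74, SE 0.185, adjusted p = 0.00236) and Fam20a (-2.09, SE 0.244, adjusted p = 0.00442). The mitochondrial gene mt-Nd3 and the ribosomal protein gene copy Rps3a3 were also lower (-2.51, SE 0.207, adjusted p = 5.51e-04 and -4.75, SE 0.438, adjusted p = 9.87e-04). The sequence of mt-Nd3 is near-identical to a nuclear copy, so its value is uncertain. Whether Rps3a3 shares reads with other copies of its gene was not tested, so its value is uncertain too. Mitochondrially encoded genes passed camera downward (median -0.21, adjusted p = 0.00273; adjusted p = 0.708 with an estimated correlation) with mt-Nd3 as the 1 gene called among 13, as it was adjusted over the list alone. Without NC-GFP replicate 1 the list did not pass (adjusted p = 0.0682).

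Genes of the response to interferon were among those that rose. The guanylate-binding protein genes Gbp3 (129 ± 8.11 to 309 ± 70.6 CPM, n = 3 each; 1.26, SE 0.185, adjusted p = 0.00821) and Gbp10 (1.92, SE 0.283, adjusted p = 0.00821) rose, as did the complement inhibitor gene Serping1 (14.6 ± 2.42 to 76.2 ± 6.28 CPM, n = 3 each; 2.38, SE 0.323, adjusted p = 0.00758) and the transcription factor gene Batf2 (1.58, SE 0.209, adjusted p = 0.00666). Without NC-GFP replicate 3, Gbp3 (1.21, adjusted p = 0.0663) and Gbp10 (1.78, adjusted p = 0.0621) were not called. The interferon list gave 3 rises and 1 fall (Oas2, -0.87) among 23, the same adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.0428; adjusted p = 0.892 with an estimated correlation). It did not pass without NC-GFP replicate 2 or 3 (adjusted p = 0.158 and 0.128), without cKO-GFP replicate 1 or 3 (0.878 and 0.120) or without cKO-mNLS replicate 2, 3 or 4 (0.0638, 0.0570 and 0.0633). Oas2 was not called without NC-GFP replicates 1, 2 and 3 in turn (adjusted p = 0.116, 0.0669 and 0.149) or without cKO-GFP replicate 3 (0.145). The list's mean level was 7.34, 6.46 and 7.10 log2 CPM in the cKO-GFP libraries and 6.64 to 6.89 in NC-GFP. Markers of microglia had a median of -0.12 (camera adjusted p = 0.511), and blood cell genes, which include immune cells, one of 1.43 (camera adjusted p = 0.00983; 0.708 with an estimated correlation; 0.0809 without NC-GFP replicate 3).

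Of the genes linked to activated microglia, 2 rose among 19 in libraries whose blood cell genes had a median of 1.43, the same adjusted over the list alone: Lgals3, encoding a galectin (1.96, SE 0.383, adjusted p = 0.0304), and Gpnmb (2.37, SE 0.506, adjusted p = 0.0449). Their list had a median of 0.44 (camera adjusted p = 0.0247; adjusted p = 0.852 with an estimated correlation), and it did not pass without NC-GFP replicate 1 or 2 (0.0541 and 0.0579) or cKO-GFP replicate 2 (0.0560). Lgals3 was not called without NC-GFP replicates 1, 2 and 3 in turn (adjusted p = 0.128, 0.142 and 0.0768) or cKO-GFP replicates 1 and 3 (0.0617 and 0.155). Gpnmb was not called without NC-GFP replicates 1, 2 and 3 (0.167, 0.179 and 0.0964), cKO-GFP replicates 2 and 3 (0.0740 and 0.228) or cKO-mNLS replicates 1 and 2 (0.0627 and 0.0601).

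Oligodendrocyte precursor markers gave 2 rises among 13, the same adjusted over the list alone (median 0.31, camera adjusted p = 0.0278): the matrix gene Tnr (2.66, SE 0.392, adjusted p = 0.00821), and Gpr17, a receptor gene of differentiating precursors (2.03, SE 0.425, adjusted p = 0.0402). Without NC-GFP replicate 3 neither the list (adjusted p = 0.0524) nor Tnr (0.0527) was called, and the list also failed without cKO-GFP replicate 2 (0.105). Gpr17 was not called without NC-GFP replicates 2 and 3 (adjusted p = 0.106 and 0.189), cKO-GFP replicates 1, 2 and 3 (0.119, 0.0538 and 0.0967) or cKO-mNLS replicate 2 (0.0506). Markers of mature oligodendrocytes and myelin gave 0 calls among 20 in edgeR, in DESeq2, in voom and at an unadjusted p under 0.05 (median -0.18, camera adjusted p = 0.266). Cytosolic ribosomal protein genes moved up as a list (median 0.49, camera adjusted p = 1.79e-10) with 0 of 43 called by edgeR, 30 higher at an unadjusted p under 0.05, 1 in DESeq2 and 6 in voom. The mean level of the list was 7.43, 7.22 and 7.996 log2 CPM in the cKO-GFP libraries and 7.01 to 7.23 in NC-GFP, a difference of 0.45 that was 0.22 without cKO-GFP replicate 3. Nuclear genes of oxidative phosphorylation (median 0.33, camera adjusted p = 6.20e-04) gave 0 of 31, 12, 1 and 2 in the same order. Both gave 0 adjusted over the list alone. Adjusted p was 0.708 with an estimated correlation for these and for the precursor list.

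Immediate early genes passed upward (median 0.47, adjusted p = 5.29e-04) with 0 of 23 called by edgeR, 4 adjusted over the list alone, 5 at an unadjusted p under 0.05, 4 in DESeq2 and 2 in voom. Blood cell genes (median 1.43, adjusted p = 0.00983) gave 0 of 13 by edgeR and over the list alone, 1 higher at an unadjusted p under 0.05, 0 in DESeq2 and 1 in voom. Cholesterol synthesis genes (median -0.22, adjusted p = 0.00983) gave 0 of 19 by edgeR and over the list alone, 4 lower at an unadjusted p under 0.05, 2 in DESeq2 and 1 in voom. For these 3 lists the adjusted p was 0.708 with an estimated correlation. Without cKO-GFP replicate 2 the immediate early (adjusted p = 0.0910) and cholesterol lists (0.0890) did not pass, and without NC-GFP replicate 3 the blood (0.0809) and cholesterol lists (0.0731) did not. The other 16 lists did not pass, with adjusted p from 0.0888 to 0.851. They included TDP-43 and RNA-binding proteins (median -0.15, adjusted p = 0.303) and the genes with reported cryptic exons (median 0.05, adjusted p = 0.706). Gene totals do not measure whether cryptic exons were included, in this comparison or the others. The remainder were presynaptic release, glutamate receptors, voltage-gated channels, dentate granule, CA pyramidal and cortical, immature and inhibitory neurons, mature oligodendrocytes, microglia, endothelial and mural cells, integrated stress, p53, heat shock, and lysosome and autophagy.

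In total, 333 of 20379 genes differed between cKO-GFP and NC-GFP, 108 higher and 225 lower, by edgeR. DESeq2 gave 1391 (652 higher and 739 lower) and voom 1506 (684 and 822), nearer to an even division. Of the lists 14 passed camera, 7 in each direction. With an estimated correlation 0 of 30 lists passed camera (1 at an unadjusted p under 0.05), and fry gave 0. The count of genes fell to 144, 93 and 61 without NC-GFP replicates 1, 2 and 3, and to 142 and 68 without cKO-GFP replicates 1 and 3, and it was 755 without cKO-GFP replicate 2. Of 35 called genes that the rule takes, more than are printed here, 18 kept the call with any 1 library left out, and 5 of the 14 lists kept theirs, the astrocyte, ribosomal, long-intron, oxidative phosphorylation and synaptic adhesion lists.

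**Figure D2:**
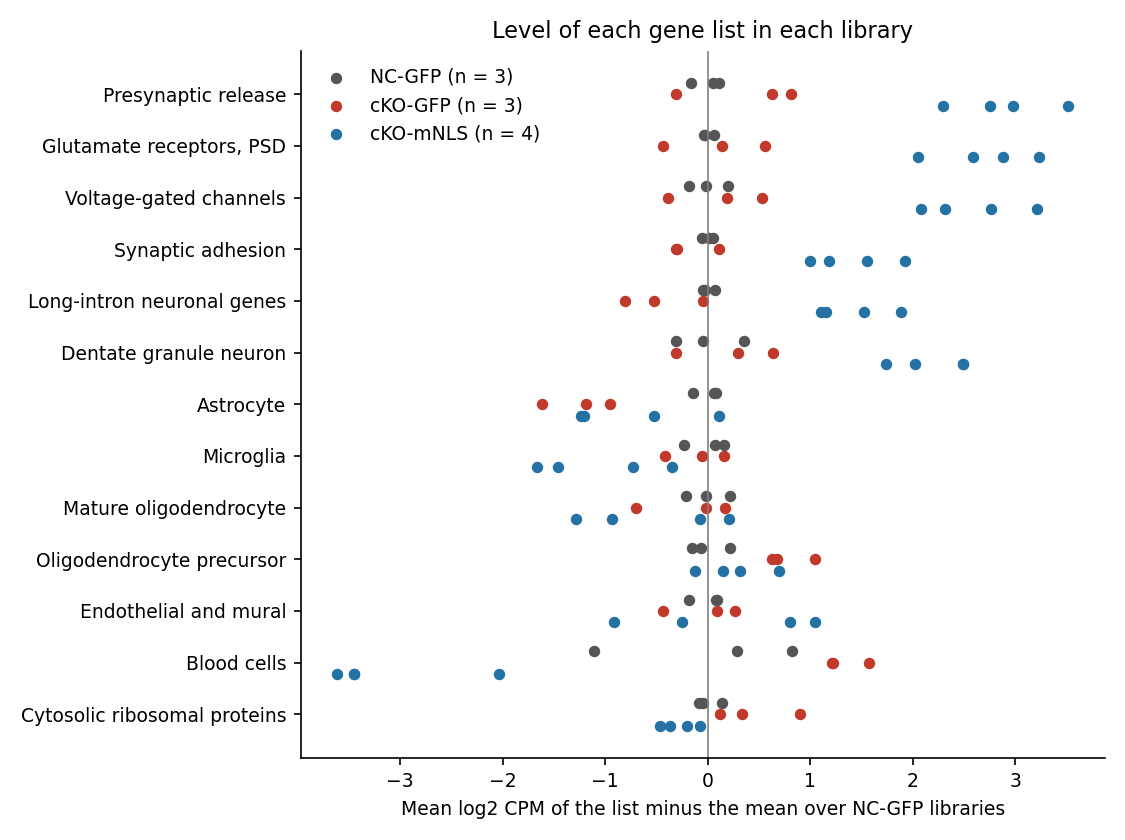
Mean log2 CPM of 13 gene lists in each library, given as the difference from the mean of the 3 NC-GFP libraries; each point is 1 library. The 6 lists of neuronal genes lie above the other groups in all 4 cKO-mNLS libraries, and the astrocyte list lies below 0 in all 3 cKO-GFP libraries.

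The effect of the TDP-43mNLS vector within TDP-43cKO mice was read from cKO-mNLS against cKO-GFP. Most genes of synapses, channels and excitatory neurons rose, and immature and inhibitory neuron genes did not follow. Among 31 genes of glutamate receptors and the postsynaptic density, 28 rose (29 adjusted over the list alone; median 2.54), and among 32 presynaptic release genes 27 rose (28 adjusted over the list alone; median 2.75). Voltage-gated channels gave 27 rises among 33 (29 adjusted over the list alone; median 2.71). The scaffold gene Bsn of the presynaptic active zone went from 20.1 ± 2.42 (SD, n = 3) to 217 ± 113 (SD, n = 4) CPM (3.43, SE 0.373, adjusted p = 0.00143). The sodium channel gene Scn2a went from 3.78 ± 1.92 (SD, n = 3) to 104 ± 61.6 (SD, n = 4) CPM (4.78, SE 0.547, adjusted p = 0.00143). The postsynaptic scaffold gene Shank2 rose from 8.80 ± 4.74 (SD, n = 3) to 79.7 ± 21.98 (SD, n = 4) CPM (3.18, SE 0.396, adjusted p = 0.00167). These 3 lists passed camera with adjusted p of 4.67e-31, 2.07e-28 and 2.92e-28, and the adjusted p was 0.0586 with an estimated correlation for each.

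GABA receptor genes gave 12 rises among 15 (13 adjusted over the list alone; median 2.93, camera adjusted p = 1.31e-15), and the adjusted p was 0.0607 with an estimated correlation. Long-intron neuronal genes gave 28 among 38 (30 adjusted over the list alone; median 1.48, camera adjusted p = 9.47e-23), with adjusted p = 0.0607 with an estimated correlation. Synaptic adhesion genes gave 28 among 35 (31 adjusted over the list alone; median 1.37, camera adjusted p = 1.11e-20) and axon-glia contact genes 18 among 37 (20 adjusted over the list alone; median 0.94, camera adjusted p = 1.54e-12), both at adjusted p = 0.0682 with an estimated correlation. Lgi1 rose by 1.99 (SE 0.232, adjusted p = 0.00143), to 43.3 ± 9.49 (SD, n = 4) CPM. Markers of dentate granule neurons gave 10 rises and 1 fall among 17 (11 and 1 adjusted over the list alone; median 1.93, camera adjusted p = 1.48e-06; adjusted p = 0.0701 with an estimated correlation). The calcium-binding protein gene Calb1 led them, from 0.93 ± 0.106 (SD, n = 3) to 20.3 ± 8.79 (SD, n = 4) CPM. By summed CPM, which abundant members dominate, the dentate list did not rise (means 1412, 1479 and 1341 in NC-GFP, cKO-GFP and cKO-mNLS). The long-intron sum was 2551, 1538 and 2531 in that order, and the presynaptic sum 536, 530 and 2280. CA pyramidal and cortical neuron markers gave 12 rises among 17 (13 adjusted over the list alone; median 1.95, camera adjusted p = 8.62e-08; adjusted p = 0.0586 with an estimated correlation). In the same libraries microglial markers moved the other way, with a median of -0.89.

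Of 18 microglial markers 10 fell (12 adjusted over the list alone), Tmem119 among them (160 ± 55.6 to 63.0 ± 15.5 CPM, n = 3 and 4; -1.34, SE 0.249, adjusted p = 0.00542). The list passed camera (adjusted p = 2.07e-08; adjusted p = 0.290 with an estimated correlation). All 13 blood cell genes fell, also adjusted over the list alone (12 in DESeq2, 3 in voom), with a median of -6.04 that was the same with genes at 0 set to their bound. The adjusted p was 2.02e-11, and adjusted p = 0.0586 with an estimated correlation. The neutrophil gene S100a9, at 8.90 CPM in cKO-GFP, and the red cell heme synthesis gene Alas2, at 9.45 CPM, had 0 counts in all 4 cKO-mNLS libraries, at least 305-fold and 324-fold lower. The hemoglobin genes of this list have close copies, and whether reads are shared among them was not tested. Cytosolic ribosomal protein genes gave 35 falls among 43 (41 adjusted over the list alone; median -0.75, camera adjusted p = 1.73e-18; adjusted p = 0.290 with an estimated correlation).

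Further falls were seen for Zfp36l2, an RNA decay factor gene (310 ± 50.7 to 128 ± 6.72 CPM, n = 3 and 4; -1.28, SE 0.136, adjusted p = 0.00143) and the phosphatase gene Dusp6 (-1.19, SE 0.132, adjusted p = 0.00143). Immediate early genes gave 11 falls and 5 rises among 23 (12 and 5 adjusted over the list alone). Their median was -0.64, their mean 0.11 and their test negative (camera adjusted p = 0.0103; adjusted p = 0.576 with an estimated correlation; 0.131 without cKO-GFP replicate 2). Fos fell by 1.46 (SE 0.228, adjusted p = 0.00272). Immature neuron and progenitor genes gave 6 falls and 2 rises among 14, the same adjusted over the list alone (median -0.64, camera adjusted p = 0.0219; adjusted p = 0.0917 with an estimated correlation), with the cell division gene Top2a at -2.21 (SE 0.342, adjusted p = 0.00266). Astrocyte markers gave 2 rises among 16 (4 adjusted over the list alone; median 0.58, camera adjusted p = 0.00747; adjusted p = 0.615 with an estimated correlation). They were the glutamate transporter gene Slc1a2 (1.01, SE 0.303, adjusted p = 0.0418) and Clu (1.46, SE 0.307, adjusted p = 0.00958). Without cKO-mNLS replicate 1 the astrocyte list did not pass (adjusted p = 0.148). Slc1a2 was not called without NC-GFP replicates 1, 2 and 3 in turn (adjusted p = 0.0505, 0.0532 and 0.0635), cKO-GFP replicates 1 and 3 (0.142 and 0.115) or cKO-mNLS replicates 1 and 3 (0.0935 and 0.0875).

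TDP-43 and other RNA-binding proteins gave 6 rises and 1 fall among 24 (7 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.0103; adjusted p = 0.290 with an estimated correlation). The neuronal splicing regulator genes Celf4 (3.14, SE 0.427, adjusted p = 0.00187) and Rbfox1 (3.54, SE 0.5, adjusted p = 0.00198) rose, in libraries where presynaptic release genes had a median of 2.75. Mitochondrially encoded genes passed upward with 0 of 13 called by edgeR and over the list alone, 4 at an unadjusted p under 0.05, 4 in DESeq2 and 2 in voom (median 0.37, adjusted p = 0.0138). Cholesterol synthesis genes gave 2 falls among 19 (0 adjusted over the list alone; median -0.28, adjusted p = 0.0219). Both had adjusted p = 0.615 with an estimated correlation. The mitochondrial list did not pass without cKO-mNLS replicate 1 (adjusted p = 0.0608), nor the cholesterol list without cKO-GFP replicate 1 (0.345) or cKO-mNLS replicate 2 (0.123). The other 12 lists had adjusted p from 0.0599 to 0.853, among them mature oligodendrocytes (median -0.28, adjusted p = 0.155), where Enpp2, also expressed in choroid plexus, was the 1 gene that rose (1.52, SE 0.311, adjusted p = 0.00836). The cryptic exon list gave 2 rises and 2 falls among 16, the same adjusted over the list alone (median 0.04, adjusted p = 0.853).

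In all, 3273 genes differed between cKO-mNLS and cKO-GFP, 1819 higher and 1454 lower. The count was 1625 without cKO-GFP replicate 1 and 1178 without cKO-GFP replicate 3. Of the 30 lists 18 passed camera, 12 upward and 6 downward. With an estimated correlation 0 passed (11 at an unadjusted p under 0.05), and fry gave 14.

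The remaining comparison set cKO-mNLS against NC-GFP. Genes of synapses and channels were higher here too, while immature neuron genes gave 5 falls and 2 rises (median -0.73) and inhibitory neuron genes 2 of each (median 0.65), without passing. Presynaptic release gave 26 rises among 32 (29 rises and 1 fall adjusted over the list alone; median 2.81, camera adjusted p = 1.40e-32), glutamate receptors 23 among 31 (24 adjusted over the list alone; median 2.02, camera adjusted p = 2.15e-29) and channels 25 among 33 (25 adjusted over the list alone; median 2.66, camera adjusted p = 1.38e-25), all at adjusted p = 0.110 with an estimated correlation. The synaptic vesicle calcium sensor gene Syt1 stood at 159 ± 87.7 (SD, n = 4) against 2.52 ± 0.88 (SD, n = 3) CPM (5.97, SE 0.677, adjusted p = 7.61e-04), and the endosomal gene Nsg2 of neurons rose by 3.29 (SE 0.254, adjusted p = 1.82e-04). GABA receptors gave 10 rises and 1 fall among 15, the same adjusted over the list alone (median 2.02, camera adjusted p = 1.02e-08; adjusted p = 0.194 with an estimated correlation). Long-intron genes gave 16 rises among 38 (20 rises and 1 fall adjusted over the list alone; median 0.69, camera adjusted p = 3.20e-08; adjusted p = 0.271 with an estimated correlation). Synaptic adhesion gave 17 rises and 1 fall among 35 (22 and 1 adjusted over the list alone; median 0.95, camera adjusted p = 1.04e-10) and axon-glia contact 12 rises among 37 (13 adjusted over the list alone; median 0.34, camera adjusted p = 7.88e-07), both at adjusted p = 0.222 with an estimated correlation. Dentate granule markers gave 6 rises among 17 (11 rises and 1 fall adjusted over the list alone; median 1.70, camera adjusted p = 7.84e-06; adjusted p = 0.179 with an estimated correlation). CA and cortical markers gave 9 rises and 1 fall among 17 (10 and 1 adjusted over the list alone; median 1.36, camera adjusted p = 6.27e-05; adjusted p = 0.110 with an estimated correlation).

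Microglial markers and most astrocyte markers were lower on average in cKO-mNLS than in NC-GFP, and oligodendrocyte precursor markers were not (median 0.00). Microglial markers gave 8 falls among 18 (14 adjusted over the list alone; median -1.05, camera adjusted p = 1.14e-10; adjusted p = 0.253 with an estimated correlation), with P2ry12 at -1.61 (SE 0.353, adjusted p = 0.0131). The P2ry12 call was lost without NC-GFP replicate 2 (-1.53, adjusted p = 0.0532) and without NC-GFP replicate 3 (-1.58, adjusted p = 0.0512). Astrocyte markers gave 4 falls among 16 (7 falls and 1 rise adjusted over the list alone; median -0.61, camera adjusted p = 2.16e-05; adjusted p = 0.468 with an estimated correlation), and Gja1 was at 166 ± 55.3 (SD, n = 4) CPM (-1.46, SE 0.225, adjusted p = 0.00195). The mean level of the astrocyte list was 7.223 log2 CPM in cKO-mNLS replicate 1, above the 6.969 to 7.198 of NC-GFP. It was 5.876 to 6.592 in the other cKO-mNLS libraries. Mature oligodendrocyte and myelin genes passed downward (median -0.46, camera adjusted p = 0.0117; adjusted p = 0.722 with an estimated correlation), yet the 1 gene called among 20, over the list alone too, was Enpp2, which rose (2.10, SE 0.319, adjusted p = 0.00181). That list was not called without NC-GFP replicate 1 (adjusted p = 0.0665), without cKO-mNLS replicate 1 (adjusted p = 0.146) or without cKO-mNLS replicate 2 (adjusted p = 0.0890). Cholesterol synthesis gave 7 falls among 19 (10 adjusted over the list alone; median -0.50, camera adjusted p = 2.01e-06; adjusted p = 0.277 with an estimated correlation), led by Mvd (-1.75, SE 0.347, adjusted p = 0.00718) and Msmo1 (-1.18, SE 0.237, adjusted p = 0.00751).

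Blood cell genes gave 7 falls among 13 (10 adjusted over the list alone; 9 in DESeq2, 2 in voom; median -4.25, the same with genes at 0 set to their bound; camera adjusted p = 3.65e-07, adjusted p = 0.110 with an estimated correlation). Oxidative phosphorylation genes gave 6 rises among 31 (10 adjusted over the list alone; median 0.29, camera adjusted p = 4.09e-04; adjusted p = 0.468 with an estimated correlation), for example Cox6c (0.73, SE 0.126, adjusted p = 0.00343). Ribosomal protein genes passed downward (median -0.26, camera adjusted p = 4.00e-04; adjusted p = 0.722 with an estimated correlation) with 0 of 43 called by edgeR, over the list alone, by DESeq2 and by voom, and 4 lower at an unadjusted p under 0.05. Rps3a3 (-6.34, SE 0.427, adjusted p = 7.36e-05) and mt-Nd3 (-2.14, SE 0.184, adjusted p = 3.47e-04) were low as in cKO-GFP, with the same doubt about shared reads. The other 14 lists had adjusted p from 0.0542 to 1.00. In this comparison 2341 genes differed, 1678 higher and 663 lower, and the count was 1521, 1255 and 1217 without NC-GFP replicates 1, 2 and 3. Of the 30 lists 16 passed, 10 upward and 6 downward. With an estimated correlation 0 passed (7 at an unadjusted p under 0.05), and fry gave 15.

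Genes that changed in cKO-GFP against NC-GFP and moved back in cKO-mNLS were counted across the comparisons. There were 166 by edgeR, of which 118 fell and then rose and 48 rose and then fell, 669 with DESeq2 and 732 with voom. Of them 17 still differed between cKO-mNLS and NC-GFP and 149 were not called there. In the same comparisons the astrocyte list had medians of -1.30 and then 0.58, and the presynaptic list 0.36 and then 2.75. The count therefore does not tell a change within cells from a change in the share of cell types. Fut9 moved by -2.25 and then 1.83 (SE 0.159, adjusted p = 0.00143), and Lgi1 by -1.94 and then 1.99. Cspg5 (1.05, SE 0.163, adjusted p = 0.00263), Mfge8 (0.61, SE 0.163, adjusted p = 0.0261), Slc7a11 (0.76, SE 0.171, adjusted p = 0.0124) and the lipid receptor gene S1pr1 (0.74, SE 0.203, adjusted p = 0.0299) also rose after falling, and each stayed lower than in NC-GFP, at -0.70, -1.09, -0.98 and -1.12. Independent lists of these sizes would share 20.08 genes that fell and then rose and 7.71 that rose and then fell. At an unadjusted p under 0.05 the real groups shared 1649 and simulated unchanged groups at most 243. The simulated groups differed in neither comparison, so this shows that the real groups differ and not that genes moved back. By edgeR's adjusted p the simulated groups shared 0 in 20 simulations, which gives no yardstick, since at most 1 gene was called in either comparison. Part of the excess may come from the 3 cKO-GFP libraries that both comparisons use, which cannot be split with 2 in each part. The count was 80, 48 and 34 without NC-GFP replicates 1, 2 and 3, 41 and 23 without cKO-GFP replicates 1 and 3, and 521 without cKO-GFP replicate 2.

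Long genes were compared because TDP-43 binds long introns. The 2038 tested genes spanning at least 113.3 kb had a median log2 fold change of -0.10 in cKO-GFP against NC-GFP, where other genes had 0.06 (camera p = 0.00111; p = 0.225 with an estimated correlation). In cKO-mNLS against cKO-GFP the medians were 0.39 and -0.04 (camera p = 1.76e-11; p = 0.0243 with an estimated correlation). Against NC-GFP they were 0.15 and -0.04 (camera p = 3.49e-05; p = 0.149 with an estimated correlation). The presynaptic list rose in the same comparisons with cKO-mNLS, with medians of 2.75 and 2.81. In cKO-GFP against NC-GFP, 2038 far shorter genes (median span 2.1 kb) had a median of -0.188, so medians did not follow span throughout. Of these shorter genes 14 were called as falling, and of the 2038 longest genes 58.

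**Figure D3:**
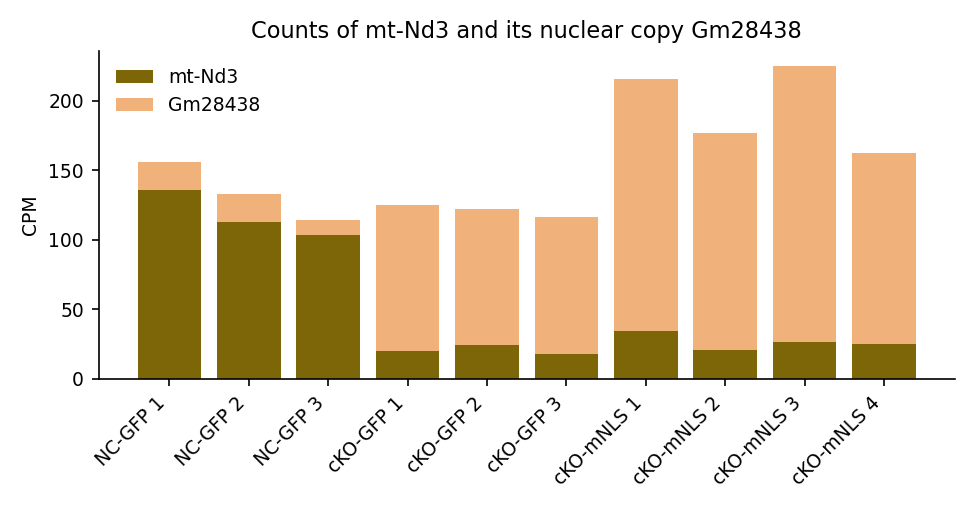
CPM of mt-Nd3 and of Gm28438, its copy on chromosome 1, stacked for each of the 10 libraries. Gm28438 holds 9.6% to 14.85% of the summed counts in NC-GFP and 80.25% to 88.4% in the 7 TDP-43cKO libraries.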

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

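Some of the key genes examined in this part had been chosen after their values were seen, and the values are given without an explanation. Each gene list level, key gene and library measure in the 4 cKO-mNLS libraries was examined for a library far from the other 3. The library measures were total counts, genes with counts, and the shares of mitochondrial and of the most abundant genes. Of the 53 values 2 stood apart, where chance flags about 1 in 20. The mean level of the blood cell list was 1.853 log2 CPM in cKO-mNLS replicate 2 and 0.28 to 0.448 in the other 3 libraries. The gap was 0.893 of the range. The mean level of the interferon response list was 7.223 log2 CPM in cKO-mNLS replicate 4 and 6.662 to 6.755 in the other 3, a gap of 0.834 of the range.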

How the results depend on the processing

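The covariate fits and the fit without mitochondrial genes were chosen only after the results were seen. No setting turned the direction of Tardbp or of another named gene here in the settings run for it, and the covariate fits are given by gene for Tardbp alone. Genes changed in cKO-GFP against NC-GFP numbered 333, and 1391 with the DESeq2 Wald test, 1506 with voom quality weights, 754 with only the compared groups and 11 with the astrocyte covariate (1771 at an unadjusted p under 0.05). Left-out libraries gave 61 to 755. For cKO-mNLS against cKO-GFP the count was 3273, then 1676 with the astrocyte and 0 with the presynaptic covariate by edgeR (935 at an unadjusted p under 0.05), with 1178 to 3629 over left-out libraries. For cKO-mNLS against NC-GFP it was 2341, then 3567 with DESeq2 and 0 with the presynaptic covariate (892 at an unadjusted p under 0.05), with 1217 to 2603. The genes that moved back numbered 166, then 669 with DESeq2, 732 with voom, 1 with the astrocyte covariate and 0 with the presynaptic covariate, with 23 to 521. The presynaptic covariate turned the sign of 682 of 3273 and 649 of 2341 calls, and other settings turned 0. The astrocyte level did not overlap between NC-GFP (6.97 to 7.20) and cKO-GFP (5.50 to 6.16), nor the presynaptic level between cKO-mNLS (4.92 to 6.14) and the other groups (2.32 to 3.44), so in those comparisons the covariate fits cannot separate level from group and decide nothing. In simulations DESeq2 called many unchanged genes and voom did not (4.1% of calls for cKO-GFP against NC-GFP). In that comparison voom recovered 12% and 58% of genes changed by log2 fold changes of 1 and 2, and edgeR 10% and 64%. Recovery was thus similar, unlike the real counts of 1506 and 333. The simulations therefore cannot decide whether unchanged genes explain the higher count of voom. The cause of the differences was not tested.

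Tardbp was not called with the presynaptic covariate (0.69, SE 0.572 against cKO-GFP; 0.48, SE 0.637 against NC-GFP). For Tardbp left-out libraries gave 0.80 to 1.19 and 0.64 to 1.00, with the call against NC-GFP lost without NC-GFP replicate 2 (0.86) or 3 (0.80). The lists that passed, 14, 18 and 16, were 0, 0 and 0 with an estimated correlation, and fry gave 0 for cKO-GFP against NC-GFP. Left-out libraries gave 10 to 14, 16 to 22 and 15 to 18 lists. Of named genes and their settings, 3872 of 4130 values stayed on the same side of the threshold with the same direction, 174 lost and 84 gained a call.

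The replicate numbers are not stated to pair the libraries, and same-numbered libraries did not deviate together (correlation -0.145 to 0.059 across genes). With the replicate block, which also left out cKO-mNLS replicate 4, the pairing fit called 176 genes in cKO-GFP against NC-GFP, 2481 and 1926 in the other comparisons, and 99 that moved back. Leaving out that library alone gave 382, 3473, 2603 and 203.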

Other observations

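The tests of depth, of the nearest copy of mt-Nd3 in cKO-GFP, of the region around Tardbp and of other splits were planned before their results, and the other tests here were chosen only after the result was seen.

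Gfap, the intermediate filament gene of astrocytes chosen here after its values were seen, was 561 CPM in cKO-mNLS replicate 1 and 78.3 to 187 CPM in the other 3, against 43.8 ± 6.71 (SD, n = 3) in NC-GFP. In the cKO-GFP libraries it was 24.9, 92.1 and 100.2 CPM (log2 fold change 0.725, SE 0.713 against NC-GFP), unlike most astrocyte markers. The inhibitory neuron transcription factor gene Dlx1 was lower in cKO-mNLS than in NC-GFP (0.812 ± 0.162 against 6.96 ± 2.13 CPM, n = 4 and 3; log2 fold change -3.10, SE 0.424, adjusted p = 0.00122), while Cck, a neuropeptide gene, was higher (24.7 ± 17.5 against 0.125 ± 0.217 CPM; adjusted p = 0.00136).

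Most astrocyte markers were lower in cKO-GFP. With every library thinned to the smallest total, the median of the list was -1.307. CPM already scales for totals, so thinning could hardly have moved this median and is weak evidence about unequal depth. A smaller share of astrocyte RNA, from cells that the GFP gate would have to exclude, stays open (Slc1a2 went from 2062 to 674 CPM), and lower expression within astrocytes was not tested. The markers ranged from -1.96 to 0.72, and the number more than 2 SE from their median was 4 of 16, or 3 of 15 without S100b, which oligodendrocytes also express, but both counts and their bound were chosen after the values were seen, so neither decides. The 10 splits of these 6 libraries are too few for a share under 0.05, and the real split gave 333 genes where the highest other gave 0 (edgeR; up to 1541 at an unadjusted p under 0.05).

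Genes of synapses, channels and excitatory neurons rose in cKO-mNLS, while 6 of 14 immature neuron genes fell and 2 rose against cKO-GFP (camera adjusted p = 0.0219; 0.0917 with an estimated correlation). After thinning, the presynaptic median was 2.766, which is weak evidence about depth because CPM already scales for totals. A larger share of neuronal RNA in these libraries may account for the rise: the presynaptic and glutamate receptor levels moved together across the 4 libraries (SD 0.085 of their difference, where the presynaptic level alone had 0.505). More transcripts per neuron under TDP-43mNLS cannot be told apart from this in bulk libraries, with microglial markers at a median of -0.894. The real split gave the most calls in each comparison, 3273 genes against at most 1161 and 2341 against at most 336 in 35 splits. Both highest others came from the split that set cKO-mNLS replicates 1 to 3 against the rest. With 35 splits chance was made unlikely as the source of the counts but was not excluded.

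Counts were lower for mt-Nd3 (GRCm38/mm10 mitochondrial genome, 9459 to 9806) and higher for Gm28438 (chromosome 1, 24612775 to 24613119) in both TDP-43cKO groups. Reads divided differently between near-identical sequences may account for this in cKO-GFP, as 344 of 345 bases of the Gm28438 transcript are identical with mt-Nd3 and the summed CPM of cKO-GFP over NC-GFP had a log2 ratio of -0.147. In cKO-mNLS the sum was higher (0.538, SE 0.172), too close to the bound of 0.5 set for cKO-GFP for that test to decide. The sum was 162.54 to 224.78 CPM in cKO-mNLS and 114.16 to 156.05 CPM in NC-GFP. A division of reads between these genes keeps their sum only if every shared read is counted, and the counting settings are not given. Mitochondrially encoded genes summed to 22028 CPM on average in cKO-mNLS and 19596 in NC-GFP. The higher sum therefore leaves a division of reads undecided in cKO-mNLS. A mitochondrial variant that differs between the mouse lines remains a candidate source, but no reads were examined for one. Gm28438 held at least 80.25% of the sum in each of the 7 TDP-43cKO libraries and at most 14.85% in NC-GFP. These shares restate the pattern, so they do not favour this source over others. Donor sequence left around the floxed Tardbp was argued against as a source of many calls, with 3 of 226 genes within 10 Mb called against 330 of 20153 elsewhere (Fisher's exact p = 1, odds ratio 0.808, interval 0.165 to 2.41), though a small excess is not excluded.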
